A study of Homo sapiens with 4 samples.

How the data were processed

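RNA-seq was analysed from 4 libraries of human multiple myeloma cell lines: ARP1 and OCI, each as wildtype cells and as cells with YTHDF2 knocked down. The labels give the second line only as OCI, and that name is used here without expansion. Each group held 1 library, and the labels name no separate cultures, so every p-value below rests on a spread between these libraries and not between replicates. That spread may be technical. Column names of the expression table begin with a letter for the line and give the genotype, and they matched the labels of 1 library each. The number of sample columns left unmapped was 0.

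Per the labels' protocols, total RNA of high integrity was extracted with Trizol, poly(A) RNA was isolated on poly-T beads and fragmented, and paired-end reads were taken on an Illumina NovaSeq instrument. The same protocol text speaks of RNA from an adipose type, which these lines are not, and small structured RNAs and replication-dependent histones, normally without poly(A), were abundant, so how far the protocol describes these libraries is uncertain. Per the submitters' processing notes, the tools were Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0, with no role or order stated. The same notes name mm8, which is a mouse build, while the genes carry human Ensembl IDs; the human build is not given in the sources used here, so no coordinates are printed. The authors deposited the values as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), with the unit taken from the table's name. The annotation, any filter, the use of strand and the total used for scaling are not given in the sources used here. Because FPKM divides by transcript length, RNAs of about the fragment size or shorter take very high or unstable values, and genes with near-identical copies depend on how shared reads were assigned.

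The table held 58229 genes. Of these IDs, 57518 were found in the gene name table and 41822 had a symbol; 57966 were in GENCODE release 29, which gave gene types and exon lengths, and 263 were not. The table holds no counts. Among single-transcript genes longer than 3000 nt, the low FPKM values fell within 0.15 of whole multiples of 1 fragment for 93.4% of 167 genes in ARP1 wildtype, 97.0% of 167 in ARP1 knockdown, 94.2% of 154 in OCI wildtype and 96.7% of 152 in OCI knockdown. These steps imply 7995158, 12275570, 18110859 and 19558577 fragments in that order. At those depths 1 FPKM in a transcript of 3 kb stands for 24.0, 36.8, 54.3 and 58.7 fragments. An exact 0 can be a failed estimate; no protein-coding gene was listed at 0 in 1 library while the others were at 5 FPKM or more.

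Differences were taken as log2(FPKM + 1), knockdown minus wildtype, which understates the change of genes at low levels. Within a line no test is possible, so genes were counted by a rule of size: a difference of at least 1 (2-fold on this scale) among genes at 1 FPKM or more in either library of the pair. The overlap of the lines was set beside the overlap of independent lists. Across lines, limma 3.58.1 in R 4.3.3 was fitted with trend to log2(FPKM + 1) of genes at 1 FPKM or more in at least 2 libraries, with line and genotype as terms, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. This model pairs the libraries by cell line, as the labels give it, and has 1 residual degree of freedom. That residual is the difference between the lines in their response, which can be technical or biological. The prior degrees of freedom of the model came out as infinite, so each gene's spread was taken entirely from the trend with expression level. A call thus acts much like a threshold on the mean difference, and a gene whose lines differ strongly can still be called. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.

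The 45 gene lists, the rule for naming genes, the tests and most alternatives were fixed before the data were examined. The lists hold 759 names, of which 752 matched, for 740 genes. Some lists share genes, so agreement between them can rest on the same genes. They cover the m6A machinery, mRNA decay, STAT and ERK signalling, both branches of the unfolded protein response, immunoglobulins, metabolism, the cell cycle, stress and antigen presentation, and markers of plasma cells and of other cell types. A list's median difference was placed among 10000 random lists of the same size matched on mean expression in 20 level bins, as a description of these libraries and not a test; a list under percentile 2.5 or over 97.5 is called apart. Lists with under 3 measured members were described by level. List medians are given relative to the median of all measured genes in the same pair, because rescaling each library to a fixed total FPKM without immunoglobulin and mitochondrial genes moved that median from -0.12 to 0.78 in ARP1 and from -0.01 to 0.39 in OCI. Small structured RNAs held most of each total, so that rescaling follows them more than mRNA.

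Named genes were YTHDF2, STAT5A, MAP2K2 and the m6A list; the 12 highest and 12 lowest genes passing the size rule in both lines at 5 FPKM or more in each line, ranked by the smaller difference; the 8 largest differences each way per line; up to 4 members per list by mean absolute difference; the 10 genes highest in each line by the smaller of the wildtype and knockdown differences; the 5 smallest adjusted p of each limma result; and the 6 genes with the largest opposite differences. The same rule was repeated over protein-coding genes alone, a step chosen after many short non-coding RNAs and pseudogenes were seen to fill the first places. Genes with near-identical copies, among them small nuclear RNAs, processed pseudogenes and their parent genes, histones and the immunoglobulin and HLA families, and antisense transcripts are uncertain throughout.

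The limma step was tested on simulated data with 13293 genes, 50 each changed 2-, 4-, 8- and 16-fold. With counting noise and a simulated noise SD of 0.158 on the log2 scale, below the spread of the real fit, limma recovered 92, 98, 100 and 100% of them and called 39 of 13093 unchanged genes. The size rule in both lines recovered 6, 78, 96 and 94% and passed 0. With each gene given the spread that the real fit took from the trend (SD 0.311 to 0.833, median 0.337), a repeat chosen after the results were seen, limma recovered 26, 70, 90 and 92% and called 5 unchanged genes. The size rule recovered 20, 68, 96 and 94% and passed 20. At this spread most 2-fold changes are missed. The simulated noise of each gene followed the trend exactly, as the fit assumes, so the 5 do not estimate the false calls of the real fit. The placing of lists was tested on 100 simulated lists of 20 genes in OCI: 4% were called apart with no shift, 80% with a log2 shift of 0.25 and 100% with 0.5. The share with no shift follows from the limits, and simulated lists do not show how genes that vary together behave. The test was not run in ARP1, where differences spread more (SD 0.60 against 0.38 in OCI), so the sensitivity there is not known. The alternatives were pseudocount 0.1, a minimum of 5 FPKM or none, a 1.5-fold threshold, median-ratio scaling, rescaling to a fixed total with and without immunoglobulin and mitochondrial genes, limma without trend or with the other factor left out, and, after the data were seen, protein-coding genes alone, removal of trends with exon length (lowess, fraction 0.4) and level, and random lists matched on length too.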

Results

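Gene expression was measured in 2 human multiple myeloma cell lines, ARP1 and OCI, with and without knockdown of YTHDF2. YTHDF2 is a reader protein that binds N6-methyladenosine in mRNA and promotes the decay of the bound transcripts. The 4 libraries were ARP1 wildtype, ARP1 knockdown, OCI wildtype and OCI knockdown, 1 of each, so differences within a line have no replicate check. Implied depths were 7995158, 12275570, 18110859 and 19558577 fragments in that order, and 13068, 13097, 12773 and 13034 genes reached 1 FPKM. Small structured RNAs such as RN7SL1, RMRP and RN7SK held 83.5, 76.7, 81.0 and 77.6% of all FPKM, and protein-coding genes 12.1, 18.8, 15.7 and 18.6%.

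The ARP1 wildtype library stood apart from the other libraries. Of measured protein-coding genes, 9.90% differed at least 2-fold between it and the ARP1 knockdown library, 10.6% between it and OCI wildtype and 12.2% between it and OCI knockdown. The remaining pairs differed at 5.14% (ARP1 knockdown and OCI wildtype), 3.47% (both knockdown libraries) and 2.70% (both OCI libraries). Short transcripts were relatively more abundant in ARP1 wildtype: the ARP1 knockdown minus wildtype median was -0.50 in the shortest of 10 length bins of protein-coding genes and 0.13 in the longest. In OCI the same medians were -0.08 and 0.02.

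**Figure D1:**
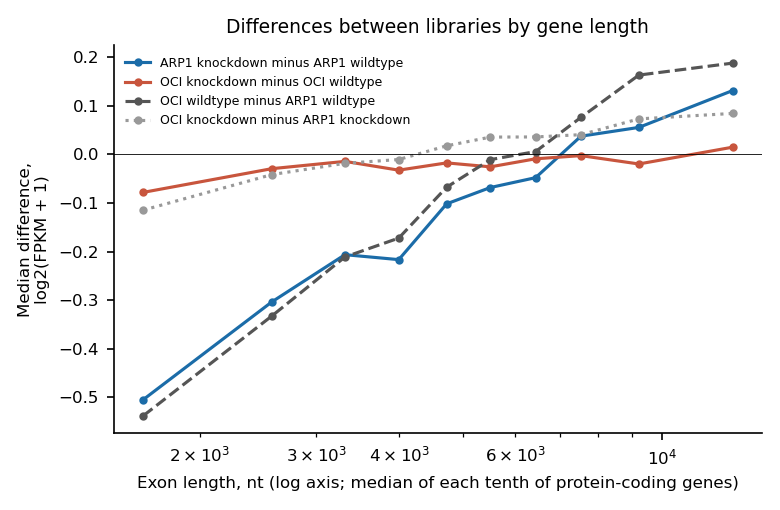
Median log2(FPKM + 1) difference (y axis) of protein-coding genes in 10 bins of exon length (x axis, nt, log scale) for 4 pairs of libraries, each point 1 bin. Both comparisons with the ARP1 wildtype library slope from about -0.50 and -0.54 in the shortest bin to 0.13 and 0.19 in the longest, and the others stay within -0.11 and 0.08.

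The targeted gene was examined first. YTHDF2 (ENSG00000198492) was lower in both knockdown libraries: 28.7 against 10.4 FPKM in ARP1, with 36.3% left, and 35.8 against 10.1 FPKM in OCI, with 28.3% left. The log2 differences were -1.38 and -1.73, with 95% counting half-widths of 0.16 and 0.12 that cover counting error only. Across lines limma gave -1.55 (SE 0.32, adjusted p = 0.00042). With values rescaled to a fixed total without immunoglobulin and mitochondrial genes the ARP1 difference was -0.14, against a median gene at 0.78 under that scaling, or -0.93 relative to it. STAT5A (ENSG00000126561), a cytokine-activated transcription factor, stood at 6.29 and 6.97 FPKM in ARP1 wildtype and knockdown and at 7.58 and 10.3 FPKM in OCI (limma 0.26, adjusted p = 0.91). MAP2K2 (ENSG00000126934), the kinase MEK2 upstream of ERK, stood at 239 and 118 FPKM in ARP1 and 168 and 128 FPKM in OCI (limma -0.70, adjusted p = 0.43). It passed the size rule as lower in ARP1 and not in OCI. With median-ratio scaling 0 members of the list of RAS-ERK pathway members, MAP2K2 included, passed as lower in ARP1.

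**Figure D2:**
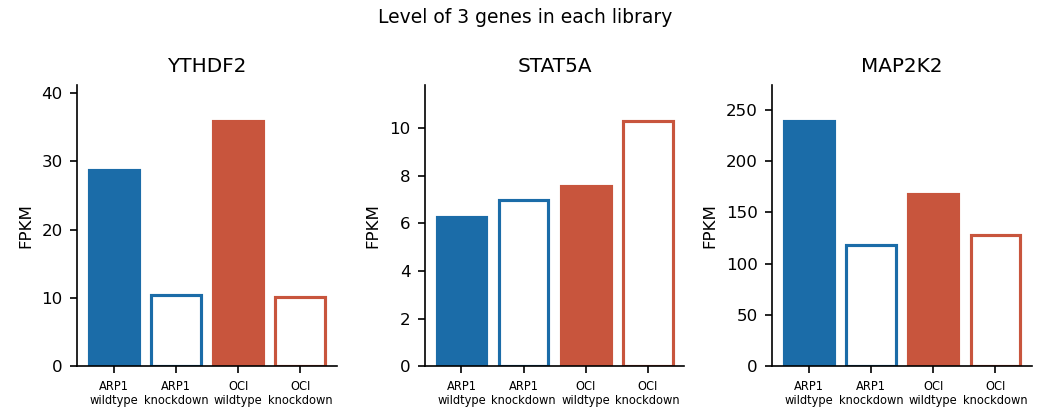
FPKM (y axis) of YTHDF2, STAT5A and MAP2K2 in each of the 4 libraries, 1 bar per library, filled for wildtype and open for knockdown. YTHDF2 falls from 28.7 to 10.4 in ARP1 and from 35.8 to 10.1 in OCI, and no error bars are drawn because each group has 1 library.

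The m6A list holds writers, erasers and readers of this mark. No member besides YTHDF2 passed the size rule in OCI, and in ARP1 the reader YTHDF3 did, at 5.85 and 14.8 FPKM (1.21); its OCI levels were 13.6 and 15.1 FPKM. IGF2BP2, a reader that stabilises bound mRNA, stood at 17.0 and 30.0 FPKM in ARP1 and 18.9 and 35.2 FPKM in OCI (limma 0.82, adjusted p = 0.29). Of 21 members tested by limma, 1 was lower, YTHDF2 itself, over all genes and also adjusted over the list alone. The writers METTL3, at 21.3, 18.4, 15.7 and 17.7 FPKM, and WTAP, at 28.3, 47.5, 41.6 and 41.9 FPKM, and the eraser FTO, at 27.9, 27.2, 31.7 and 35.1 FPKM, did not pass. The list's median in ARP1 lay 0.48 above that of all genes (percentile 99.9), which became 0.27 and percentile 97.2 with length and level trends removed; in OCI it lay 0.02 above (percentile 75.2).

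In ARP1 the protein-coding gene furthest above its wildtype level in the knockdown library was FHIT, a diadenosine triphosphate hydrolase and tumour suppressor, at 5.98 and 616 FPKM. TRIM44 (4.88 and 32.3 FPKM), the growth factor binding protein IGFBP4 (13.6 and 77.4 FPKM) and the fatty acid elongase ELOVL6 (9.18 and 43.8 FPKM) were also among the highest. The lowest protein-coding genes relative to wildtype were the histone gene H4C12 (355 and 26.1 FPKM), the lens filament gene BFSP2 (9.27 and 0.119 FPKM), the mitochondrial peptidase IMMP2L (62.2 and 6.97 FPKM) and PDSS2, an enzyme of coenzyme Q synthesis (70.5 and 9.80 FPKM). HLA-DQB1, an MHC class II chain, stood at 6.31 and 0.243 FPKM. ZSCAN5A and FAM171A1 were likewise among the highest and NTNG2 and DGKG among the lowest.

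By the size rule 677 genes were higher and 1309 lower in ARP1 of 14057 measured. This split of 65.9% lower became 52.1% with median-ratio scaling (864 higher, 940 lower) and 1.24% with rescaling to a fixed total over all genes (2940 higher, 37 lower). Among protein-coding genes 303 were higher and 816 lower of 11304, and of those past the rule 83.6% were lower among the shortest when genes were divided into equal classes by exon length, 71.9% in the middle class and 52.99% among the longest. Over all gene types the largest differences belonged to short non-coding RNAs and pseudogenes, such as RNU1-3 (0 and 1163 FPKM) and RNVU1-31 (3473 and 0 FPKM), near-identical copies of U1 genes between which reads can be split.

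In OCI the largest protein-coding differences above wildtype were H2AC7, a histone gene listed at 0.0009 and 94.9 FPKM, ATP13A4 (0.197 and 13.9 FPKM), the interferon- and NF-kB-induced chemokine CXCL10 (0.865 and 18.2 FPKM) and the scaffold gene TANC2 (0.917 and 18.1 FPKM). RNF217, PDE4D and CPNE4 were also among the highest. The lowest were TMSB4X, which encodes the actin-binding peptide thymosin beta-4 (8266 and 1133 FPKM), PLA2G4B, the arginine synthesis enzyme ASS1 (65.8 and 14.0 FPKM), the branched-chain amino acid transaminase BCAT1 (9.87 and 1.65 FPKM), APBA2 and NUCB2 (33.5 and 9.54 FPKM). By the size rule 382 genes were higher and 316 lower of 13616. Among protein-coding genes 194 were higher and 107 lower of 11148. With rescaling to a fixed total over all genes the counts were 215 and 50.

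The design asks next which differences the lines shared. In both lines the homeobox repressor ZHX3 was higher in the knockdown library (4.96 and 24.7 FPKM in ARP1, 4.11 and 38.0 FPKM in OCI), as were TANC2 (3.87 and 19.7, then 0.917 and 18.1 FPKM) and DTX4, a ubiquitin ligase of the Deltex family (1.13 and 6.24, then 1.09 and 5.23 FPKM). TMSB4X was lower in both (6792 and 1955, then 8266 and 1133 FPKM), as was FOS, an immediate early component of AP-1 (30.8 and 9.103, then 11.6 and 3.24 FPKM). POU2AF1, a coactivator of B-lineage transcription (41.4 and 13.6, then 12.7 and 4.21 FPKM), and BHLHA15, a transcription factor of secretory cells (37.6 and 14.6, then 45.6 and 15.3 FPKM), were lower in both. The galectin LGALS1 stood at 2237 and 857, then 1304 and 528 FPKM.

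Shared by the size rule were 47 genes higher and 73 lower of 12900 measured in both lines, against 8.89 and 17.0 for independent lists; 74 passed in opposite directions, against 28.3. With median-ratio scaling 53 were shared higher and 64 lower, against 12.9 and 10.9. With rescaling to a fixed total over all genes, which moves the median gene up by 0.776 and 0.384 in ARP1 and OCI and so raises the number expected, 58 were shared higher and 9 lower, against 49.2 and 0.058. At 1.5-fold 193 and 365 were shared, against 118 and 201, and 328 went opposite ways, against 327.6. Of the shared genes 21 higher and 29 lower were protein-coding (3.72 and 6.36 for independent lists) and 14 protein-coding genes went opposite ways (12.9). Of the other 70 shared genes 25 were antisense to, or within, another gene, 19 pseudogenes, 15 lincRNAs or processed transcripts and 10 small structured RNAs. Among the pseudogenes and small RNAs were SNORD3D, RNVU1-28, BCYRN1, RPS27P19, RPS27P3, RPS27P4 and UBA52P6 on the lower side and RN7SL449P and SNRPGP10 on the higher side. The non-coding transcripts LINC01480 (38.0 and 7.28, then 40.03 and 12.7 FPKM), LINC00339 (15.4 and 44.9, then 6.34 and 14.8 FPKM) and PCED1B-AS1 also passed in both. Across 11507 genes at 1 FPKM or more in every library the knockdown differences of the lines correlated at Pearson r = 0.143 and Spearman rho = 0.144, with the same sign for 55.1% (88.9% with rescaling to a fixed total without immunoglobulin and mitochondrial genes, which moves most genes up in both lines); genes are not independent replicates.

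**Figure D3:**
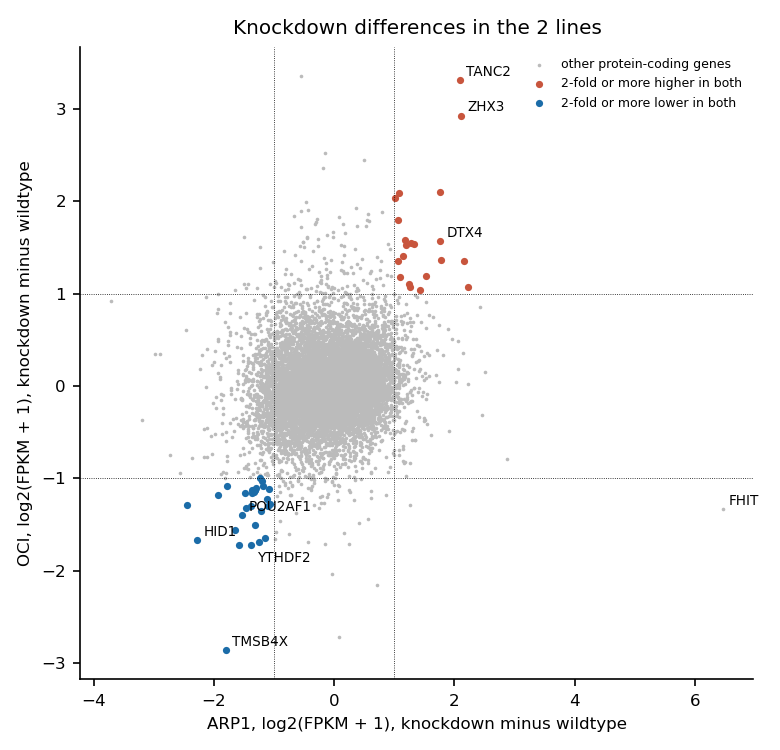
Knockdown minus wildtype differences on the log2(FPKM + 1) scale of protein-coding genes measured in both lines, ARP1 on the x axis and OCI on the y axis, each point 1 gene, with dotted lines at differences of 1 in size. The 21 genes higher in both lines are red, the 29 lower in both are blue, and FHIT lies alone at 6.46 in ARP1 and -1.34 in OCI.

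With limma, 59 genes rose and 117 fell with the knockdown of 13293 tested. The protein-coding genes with the smallest adjusted p among those with 1 sign in both lines were TANC2 (2.70, SE 0.35, limma adjusted p = 4.9e-12), ZHX3 (2.52, SE 0.33, limma adjusted p = 2.2e-11), TMSB4X (-2.33, SE 0.37, limma adjusted p = 2.2e-07) and HID1, a gene of secretory granule traffic (-1.97, SE 0.36, limma adjusted p = 1.8e-05). FOS (-1.61), POU2AF1 (-1.47), BHLHA15 (-1.41), LGALS1 (-1.34), the netrin receptor DCC (-1.65), the cold-sensing channel TRPM8 (-1.87), SPINK2 (-1.47), NXPH4 (-1.29) and the interferon-induced exonuclease ISG20 (-1.26) also fell, and DTX4 (1.67) rose. Of the 176 calls 86 were protein-coding, 93 passed the size rule in both lines and 16 had opposite signs in the lines, FHIT among them (2.56, limma adjusted p = 2.1e-12). The fit took its spread from the expression trend alone, the smallest called difference was 1.06, and without a filter on low values limma called 0 genes (878 at an unadjusted p under 0.05). With the line left out of the model limma called 5 genes, all of them lower.

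Among the gene lists, plasma cell markers were lower relative to all genes in both lines, with relative medians of -0.80 in ARP1 (percentile 0.55, 11 measured) and -0.66 in OCI (percentile 0.01, 10 measured). All 10 members measured in both lines were lower in both knockdown libraries, 3 passing the size rule in ARP1 and 2 in OCI. With limma 3 fell over all genes and 5 adjusted over the list alone. POU2AF1 passed in both lines; DERL3, a factor of endoplasmic reticulum degradation (30.1 and 14.7, then 45.1 and 13.6 FPKM, limma adjusted p = 0.0057), and the surface receptor SLAMF7 (9.02 and 1.31, then 2.75 and 1.20 FPKM, limma adjusted p = 0.015) fell by limma. MZB1, an immunoglobulin chaperone, stood at 1140 and 472, then 995 and 536 FPKM (limma adjusted p = 0.077). Counts of list members refer to the values as deposited unless a setting is named. With rescaling to a fixed total without immunoglobulin and mitochondrial genes (fixed-total rescaling), which moves the median gene up by 0.78 and 0.39, such counts change. This rescaling also makes all values smaller, so the added 1 and the 1 FPKM minimum weigh more. For the plasma cell markers it left 9 measured members, 2 of them past the size rule as higher and 0 as lower in ARP1, and 1 as lower in OCI. The ARP1 relative median became -0.39 (percentile 4.95), and -0.49 (0.49) with length and level trends removed. Under the same settings the OCI relative median was -0.50 (percentile 0.01) and -0.55 (0.00), so the list stayed low in OCI.

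Genes of folding and secretion driven by XBP1 and ATF6 had a relative median of -0.84 in OCI (percentile 0.00) and -0.40 in ARP1 (percentile 15.1). The ARP1 value was -0.023 (percentile 48.6) with length and level trends removed and -0.12 (24.7) with fixed-total rescaling. Of 21 members, 17 were lower in both lines, and 6 in OCI and 4 in ARP1 passed the size rule as lower. With fixed-total rescaling 0 passed as lower in either line and 5 passed as higher in ARP1. The OCI relative median stayed low under it, at -0.71 (percentile 0.00). With limma 2 fell over all genes, the chaperone HYOU1 (91.9 and 42.9, then 95.1 and 43.4 FPKM, limma adjusted p = 0.036) and CRELD2 (42.6 and 16.7, then 38.4 and 17.3 FPKM, limma adjusted p = 0.017), and 9 adjusted over the list alone. SEC61B stood at 372 and 211, then 395 and 190 FPKM, and MANF at 76.3 and 52.7, then 97.7 and 41.5 FPKM. The other branch, PERK and ATF4 targets, had a relative median of 0.28 in OCI (percentile 100) with 4 of 20 members higher: ATF3 (6.45 and 15.0 FPKM), DDIT3 (7.62 and 17.4 FPKM), DDIT4 (101 and 204 FPKM) and SESN2 (23.6 and 50.0 FPKM). In ARP1 that list lay at -0.36 (percentile 14.5), with 0 of 20 members higher and 2 lower, ATF3 (8.77 and 3.64 FPKM) and SHMT2 (535 and 263 FPKM, named after its values were seen), and no member passed in limma. Whether the lines differ in any list was not tested.

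Immunoglobulin constant regions and the J chain had a relative median of -0.91 in OCI (percentile 0.00, 5 of 12 lower) and -0.48 in ARP1 (percentile 7.35, 2 higher and 4 lower of 11). With fixed-total rescaling the ARP1 value was -0.12 (percentile 47.5, 4 higher and 0 lower of 9). In OCI 0 of 8 then passed, while the relative median stayed low at -0.76 (percentile 0.00). The kappa constant gene IGKC stood at 13066 and 3818, then 6484 and 2708 FPKM (limma adjusted p = 0.013) and IGHG1 at 180 and 46.2, then 73.9 and 40.4 FPKM (limma adjusted p = 0.0015), and with limma 1 member rose (IGHA1, higher in ARP1 and lower in OCI) and 2 fell over all genes, or 2 and 6 adjusted over the list alone. Also low in OCI were the cholesterol synthesis list (relative median -0.44, percentile 0.00, 2 of 20 lower), cytosolic ribosomal proteins (-0.42, percentile 1.08, 2 of 30 lower) and adhesion genes (-0.28, percentile 0.88), which lay at percentiles 81.6, 28.8 and 86.7 in ARP1. All 30 ribosomal protein genes were lower in both lines in the values as deposited. With fixed-total rescaling their median difference was 0.51 in ARP1, with 5 past the size rule as higher, and 0.097 in OCI. The list left the low range in OCI with length and level trends removed (relative median -0.06, percentile 11.3) and with fixed-total rescaling (3.46), and the adhesion list did so with the latter (2.87). NF-kB-induced genes (0.58, percentile 99.99, 3 of 13 higher, with ICAM1 at 1.84 and 5.86 FPKM), genes induced by STAT3 or STAT5 (0.26, percentile 99.7, 0 of 9 past the size rule), p53 targets (0.25, percentile 98.9), the BCL2 family (0.15, percentile 98.2) and glycolysis (0.12, percentile 99.9) lay high in OCI, the p53 list at 96.8 with fixed-total rescaling. In ARP1 these lists had relative medians of -0.23, -0.29, -0.01, -0.38 and -0.29 (percentiles 23.3, 31.8, 42.1, 11.03 and 57.7). The NF-kB and STAT values there turned to 0.24 and 0.14 with fixed-total rescaling (percentiles 79.4 and 81.4), while the others stayed negative. That rescaling left 7 of 10 measured members in both the NF-kB and the STAT list. With median-ratio scaling, which kept all 10, their values were -0.24 and -0.29. With the length trend removed the ARP1 NF-kB value was 0.070 (71.7).

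In ARP1 the other lists that lay low were MHC class II presentation (-0.92, percentile 0.00, 5 of 10 lower, with CD74 at 52.8 and 23.6 FPKM and HLA-DRA at 70.6 and 29.1 FPKM), immediate early genes (-0.71, percentile 0.04, 4 of 16 lower, with JUN at 24.9 and 6.36 FPKM), 4 measured epithelial markers (-1.03, percentile 0.22) and replication-dependent histones (-0.91, percentile 1.05, 7 of 12 lower). In OCI they lay at percentiles 14.6, 27.6, 92.2 and 92.9. The immediate early list stood at -0.44 (percentile 1.25) with the length trend removed, -0.30 (2.15) with length and level removed and -0.41 (0.15) with fixed-total rescaling. The histone list lost this place once the length trend was removed (percentile 61.2) and kept it against random lists matched on length too (2.36); in OCI it lay high with the length trend removed (99.4). Splicing factors (0.49, percentile 100), the CCR4-NOT and decay factors (0.28, percentile 97.7) and MYC targets (-0.00, percentile 99.2) lay high. High here is against random lists of like level, whose median differences were -0.44, -0.11 and -0.46. The MYC list, with a median difference of -0.13, thus fell less than genes of its level. The decay list fell inside the middle range with median-ratio scaling (97.4), with protein-coding genes only (96.1) and with each control for length (90.98 to 97.2). The MYC list, with a relative median near 0, changed its sign with pseudocount 0.1, under both scalings and with trends removed. The splicing list stood at 0.31 with the length trend removed. In OCI these lists lay at percentiles 27.3, 31.6 and 2.86. With the length trend removed the MYC list lay at 1.87 there. DNA replication genes (percentiles 99.1 and 99.2), proteasome subunits (99.8 and 97.9) and mitochondrially encoded mRNAs (99.99 and 98.6) lay high for their level in ARP1 and OCI, with relative medians of 0.12 and 0.06, 0.04 and -0.00, and 0.05 and -0.04. Random lists of like level had ARP1 median differences of -0.35, -0.47 and -0.71, against -0.001, -0.08 and -0.07 for these lists. None of their members passed the size rule as deposited. In ARP1, fixed-total rescaling left 11 of 21, 14 of 25 and 8 of 13 members past it as higher. With length and level trends removed the ARP1 relative medians were 0.28, 0.26 and 0.93, with 2, 0 and 5 members higher. The proteasome and mitochondrial medians in OCI turned positive with fixed-total rescaling. The OCI percentile lay inside the middle range for proteasome genes against protein-coding genes only, with the length trend removed and with lists matched on length too (97.2 to 97.3) and for replication genes with length and level trends removed (96.2).

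The remaining lists lay within the middle 95% of random lists in both lines, some of them not under every alternative. The list of transcripts reported as YTHDF2 targets in other cells, which includes STAT5A and so is not independent of the study, lay at percentiles 97.1 and 60.3 in ARP1 and OCI, with MYC at 691 and 424, then 631 and 420 FPKM. Its ARP1 percentile was 99.1 with pseudocount 0.1 (relative median 0.54, against 0.38) and 62.7 with fixed-total rescaling. Components of JAK-STAT signalling lay at 89.1 and 97.4, RAS-ERK pathway members at 55.9 and 54.4 and genes induced by ERK at 52.0 and 9.37. In OCI the JAK-STAT list lay at 98.1 with pseudocount 0.1 and at 97.7 with fixed-total rescaling. The ERK-induced list fell to 0.35 in OCI with length and level trends removed (relative median -0.26, against -0.12). Also within this range were the CDK inhibitors, MAF programme, nuclear respiratory chain, MHC class I, mitosis, polycomb and DNA methylation, fatty acid synthesis, heat shock, housekeeping, hypoxia, interferon, short-lived transcription factor, myeloma class and B cell lists. The interferon list fell to 0.50 in OCI with fixed-total rescaling and the mitosis list rose to 97.9 in ARP1 with length and level trends removed and 98.1 against lists matched on length too. Of 69 markers of other cell types 16 reached 1 FPKM in a wildtype library. The highest epithelial marker of each library stood at 13.3, 6.31, 16.9 and 19.7 FPKM and the highest B cell marker at 11.3, 10.3, 16.5 and 20.4 FPKM. The highest T and NK cell marker, ZAP70, reached 3.63 FPKM in ARP1 knockdown (3 members measured in ARP1, percentile 96.7, or 98.95 to 99.6 with protein-coding genes only and with the controls for length), the highest erythroid 1.68 FPKM and the highest fibroblast 3.51 FPKM in any library, and the monocyte list held CST3 at 95.4, 86.3, 118 and 92.0 FPKM.

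**Figure D4:**
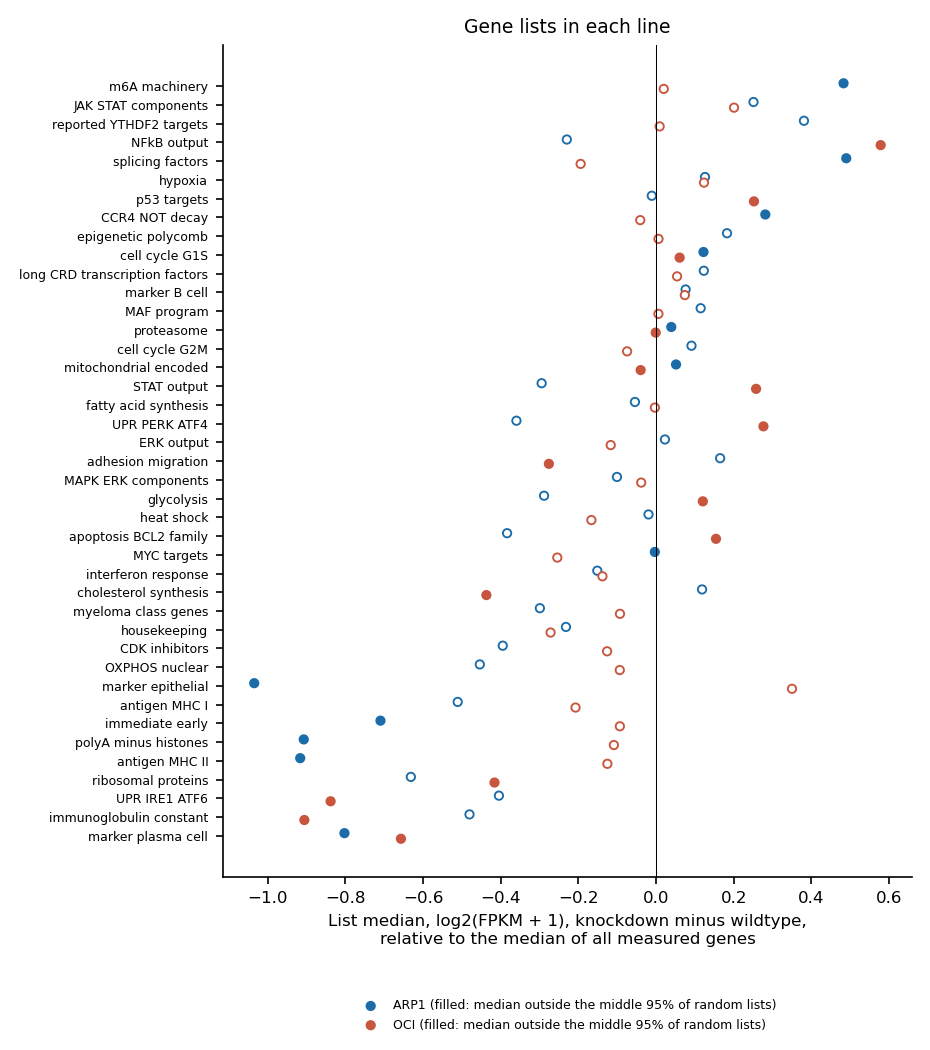
Median knockdown minus wildtype difference of each list measured in both lines on the log2(FPKM + 1) scale, relative to the median of all measured genes (x axis), for ARP1 (blue) and OCI (red); filled points lie outside the middle 95% of random lists matched on level. Plasma cell markers are filled on the low side in both lines, at -0.80 and -0.66, and rescaling to a fixed total without immunoglobulin and mitochondrial genes changes the sign for 9 lists in ARP1 and 7 in OCI.

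The lines themselves differed at a few genes of known lineage and metabolic roles. OCI expressed the immunoglobulin heavy constant genes IGHA1 (1.14 and 37.3 FPKM in ARP1 wildtype and knockdown, 4764 and 2322 FPKM in OCI) and IGHA2 (1.48, 10.0, 707 and 414 FPKM), whose near-identical sequences can share reads. ASS1 (1.47, 3.02, 65.8 and 14.0 FPKM), the lymphocyte adaptor SASH3 (25.4, 8.36, 79.6 and 60.4 FPKM) and the galectin LGALS9 (4.82, 9.06, 19.1 and 26.6 FPKM) were also higher in OCI. Higher in ARP1 were the adhesion molecule CADM2 (20.2, 14.1, 0.0715 and 0.563 FPKM), glutamine synthetase GLUL (52.8, 41.6, 5.27 and 9.04 FPKM), the protease LGMN (75.4, 76.1, 14.1 and 25.2 FPKM) and the non-coding LINC01916 (52.0, 45.6, 0 and 0 FPKM). IFITM2, ZFP90 and IL1RAP in OCI and GCSAM, RGS1, MGAT4C and SLC25A48 in ARP1 followed.

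By the size rule in both genotypes 78 genes were higher in OCI and 117 higher in ARP1, 33 and 43 of them protein-coding. With limma 102 genes were higher in OCI and 175 higher in ARP1 of 13293 tested, among them IGHA1 (8.52, limma adjusted p = 8.2e-155), CADM2 (-3.79, limma adjusted p = 4.4e-22), ASS1 (3.33, limma adjusted p = 8.6e-20), GLUL (-2.59, limma adjusted p = 8.7e-13) and SASH3 (2.16, limma adjusted p = 4.3e-09), as log2 OCI minus ARP1. Of these 277 calls 149 passed the size rule in both genotypes, and the same limits on the fitted spread apply; without a filter on low values limma called 0 genes (1149 at an unadjusted p under 0.05). With genotype left out of the model limma called 7.

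**Figure D5:**
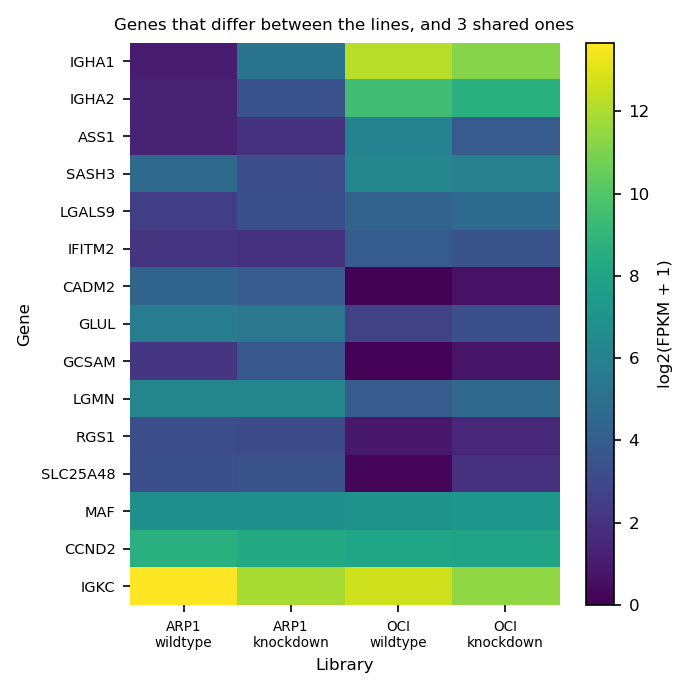
Heatmap of log2(FPKM + 1) (colour) of 15 genes in the 4 libraries: 6 higher in OCI, 6 higher in ARP1 and MAF, CCND2 and IGKC, which all libraries express. IGHA1 and IGHA2 reach 4764 and 707 FPKM in OCI wildtype and stand at 1.14 and 1.48 FPKM in ARP1 wildtype.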

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

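The comparison of IGHA1 with other genes specific to OCI was chosen after its result was seen. Of genes at 5 FPKM or more in each line, 16 with a symbol, 6 of them protein-coding, passed the size rule in opposite directions in the lines; the difference between the lines was not tested, since each has 1 library per genotype. The log2(FPKM + 1) differences, knockdown minus wildtype, follow as ARP1 and then OCI. FHIT stood at 6.46 and -1.34. The stress-induced transcription factor ATF3 stood at -1.08 and 1.11, and the clock gene PER1 at -1.001 and 1.07. TMEM187 stood at -1.47 and 1.06, the transporter SLC44A2 at -1.01 and 1.35 and C19orf81 at -1.94 and 1.002. The pseudogenes PET100P1 (-5.34 and 5.89), CDC26P1 (4.09 and -4.73) and MTCO1P12 (-1.28 and 1.42), the antisense transcript DNAJC27-AS1 (2.72 and -2.71) and the small nucleolar RNA SNORD3B-1 (1.20 and -1.24) are short, antisense or near-identical to other genes, so their values are uncertain. IGHA1 stood at 4.16 and -1.04.

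IGHA1 rose from 1.14 to 37.3 FPKM and IGHA2 from 1.48 to 10.0 FPKM between ARP1 wildtype and knockdown by the size rule, while OCI held 4764 and 2322 FPKM of IGHA1. Reads or RNA carried over from an OCI library may account for this: the ARP1 knockdown level was 1.61% of the OCI knockdown level for IGHA1 and 2.43% for IGHA2. Other genes specific to OCI would have to appear at a like share. Only 9 genes were at 10 FPKM or more in both OCI libraries and in ARP1 wildtype under 5% of the lower OCI value, and besides the IGHA pair 0 of them were longer than 500 nt, so carry-over cannot be told apart from expression in ARP1 knockdown cells for lack of genes to test.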

How the results depend on the processing

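The repeats with protein-coding genes alone, with length or level trends removed, with random lists matched on length and without the ARP1 wildtype library were chosen after the results were seen; all others were planned. Counts past the size rule are given as higher and lower, first ARP1 (677 and 1309 as reported), then OCI (382 and 316), then shared (47 and 73). With pseudocount 0.1, 1191 were higher in ARP1, 809 and 556 in OCI, and 118 and 144 were shared. With a minimum of 5 FPKM, 241 were higher in ARP1, 130 and 145 passed in OCI and 9 higher were shared. At 1.5-fold the counts were 1956 and 3450, 1159 and 1021, and 193 and 365 shared, the looser threshold being the cause. Independent lists would then share 118 and 201, so the counts were further above them in number and nearer to them as a ratio, and 328 genes went opposite ways against 327.6 (74 against 28.3 as reported). Rescaled to a fixed total over all genes they were 2940 and 37, 215 and 50, and 58 and 9 shared. This moves the median gene up in both lines, so independent lists would share 49.2 higher (8.89 as reported), and the count says little about an excess. The shared higher genes were 53 against 12.9 with median-ratio scaling and 27 against 5.73 with the length trend removed. Without immunoglobulin and mitochondrial genes they were 2995 and 37, 221 and 51, and 60 (51.2 for independent lists) and 9 shared. The cause was not tested beyond the shift that this rescaling gives the median gene. Protein-coding genes alone, a smaller set, gave 303 and 816, 194 and 107, and 21 and 29. With the length trend removed the counts were 453 and 454 in ARP1, so that the excess of lower genes was gone (removal also sets the median near 0), 197 and 100 in OCI, and 27 and 19 shared; with length and level trends removed 355 and 486, 132 and 136, and 14 and 27. Of the last 2 settings the cause was not tested apart from the smaller set. Dropping the filter left every size count as it was, since no gene under 1 FPKM in both libraries can differ by 1, and median-ratio scaling kept each count within 1.5 times.

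For the knockdown in limma (59 rose, 117 fell), a minimum of 5 FPKM gave 24 rising; without trend 70 fell; with the line left out 0 rose and 5 fell; protein-coding genes alone gave 25 and 53, and with the length trend removed 30 and 62. With no filter limma called 0 and 0 (smallest adjusted p 0.844, and 878 genes at an unadjusted p under 0.05). For the line (102 higher in OCI, 175 in ARP1), a minimum of 5 FPKM gave 56 and 101, no filter 0 and 0 (smallest adjusted p 0.781, and 1149 at an unadjusted p under 0.05), genotype left out 4 and 3, protein-coding genes alone 57 and 79, and the length trend removed 87 higher in ARP1. Fewer genes were tested at 5 FPKM and for protein-coding genes, and the spread was fitted anew in each setting. The cause of the changed counts was not tested. Of the 176 knockdown calls, 157 were called with pseudocount 0.1, 107 at 5 FPKM, 164 with median-ratio scaling, and 116 without trend. Of the 86 that are protein-coding, 74 were called among protein-coding genes alone and 70 with the length trend removed.

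The YTHDF2 difference was -0.14 in ARP1 and -1.07 in OCI when rescaled to a fixed total without immunoglobulin and mitochondrial genes, lower than wildtype as under every setting run. That rescaling also turned 4 ARP1 genes of low level below the median gene: ITGB2 (-0.32), NKG7 (-0.38), FAS (-0.29) and TP53INP1 (-0.12). The histone list in ARP1 turned from below to above the random lists' median, by 0.041 with the length trend removed and 0.15 with length and level removed, and stayed low against random lists matched on length (percentile 2.36); the cause was not tested beyond the trends removed. Of 570 list percentiles under alternatives 539 stayed on their side of the limits, 14 passed them newly, 15 no longer did and the 2 of the histone list crossed the random lists' median. This counts no change in the sign of a relative median, and no crossing of the random lists' median by a list within the limits. Of 3874 limma values of named genes the numbers were 3628, 11, 235 and 0, and of 1587 values by line 1470, 41, 72 and 4. The Pearson correlation of the lines stayed between 0.097 and 0.192, and Spearman rho between 0.095 and 0.204. The share of genes with the same sign, 55.1% as reported, was 88.9% with the rescaling that moves most genes up in both lines. Leaving out a line leaves no residual degree of freedom, and without the ARP1 wildtype library only the OCI comparison, with 698 genes past the size rule, remains. Depth limits low genes most in ARP1 wildtype, where 1 fragment in 1 kb is worth 0.125 FPKM, against 0.0511 FPKM in OCI knockdown.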

Other observations

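The test of the longest genes below was set before its result was seen; the tests of a shift at all lengths, of the ARP1 wildtype library and of the plasma cell markers were chosen after. Both lines expressed genes of the MAF class of myeloma. MAF, a transcription factor activated by translocation in a class of myeloma, stood at 110, 117, 130 and 143 FPKM in ARP1 wildtype, ARP1 knockdown, OCI wildtype and OCI knockdown, and its target CCND2 at 414, 329, 274 and 248 FPKM. The light chain genes IGKC and IGLC1 were both abundant in both lines, IGLC1 at 2052, 1350, 1523 and 1012 FPKM. MAF, CCND2 and IGLC1 were picked after their values were seen. Replication-dependent histones, normally not polyadenylated, were abundant despite the poly(A) selection named in the labels: H2BC5 stood at 4489, 2396, 2406 and 1482 FPKM.

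Some of the genes with large ARP1 differences span common fragile sites. FHIT and IMMP2L stood at log2 differences of 6.46 and -2.99 in ARP1, and at -1.34 and 0.34 in OCI. They were grouped here after their values were seen, no set of fragile-site genes was tested, and no explanation was tested.

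In ARP1, 816 of 1119 protein-coding genes past the size rule were lower in the knockdown library. A trend with gene length was tested by the share lower among the longest genes when 3 equal classes were made by exon length, which was 52.99%, between preset bounds of 50% and 60%, so length as the whole cause stays open. A shift of every gene in 1 direction, as a scaling factor gives, would lower long genes too. The median differences were -0.34 and -0.09 in the short and middle classes and 0.0613 in the longest (95% bootstrap interval 0.0371 to 0.0852). The interval resamples genes of this 1 pair as if independent and holds no spread between libraries. For this pair the change of sign argues against such a shift as the whole cause of these medians. It does not decide on the excess of lower genes past the size rule. Over all gene types median-ratio scaling gave 864 higher and 940 lower, against 677 and 1309 as deposited. That scaling also sets the ARP1 median near 0 (0.005). With the length trend removed 453 genes were higher and 454 lower, but that removal also sets the median near 0 and so does not decide. For 68.2% of the 1119 genes OCI wildtype lay closer to ARP1 knockdown than to ARP1 wildtype, and OCI knockdown did for 77.0%. These genes were chosen for the ARP1 difference and the distances between libraries were already known, so this restates that the ARP1 wildtype library stands apart. Library preparation, its lower depth and the state of the culture may each have set that library apart, and with 1 library per group these stay open. An effect of the knockdown in ARP1 does not by itself account for the 10.6% of genes that differ between the wildtype libraries; whether it adds to the ARP1 differences was not tested.

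Plasma cell markers lay low in both lines. With trends in length and level removed the higher of the lines' percentiles was 0.49, which argues against a length trend as the whole cause. For level this adds little, since the random lists were matched on level in every setting. The relative median went from -0.80 to -0.49 in ARP1 and from -0.66 to -0.55 in OCI, so part of the ARP1 value went with the trends. The ARP1 random lists' median difference went from -0.39 to -0.006. Cells of another type in the knockdown libraries would bring their own markers, and of 69 such markers, 16 of which reached 1 FPKM in a wildtype library, the largest rise was 3.89 FPKM (BACH2 in OCI, from 16.5 to 20.4 FPKM), under the bound of 10 FPKM. The transcription factors IRF4 (270, 252, 427 and 294 FPKM) and PRDM1 (128, 125, 172 and 110 FPKM), named after their values were seen, differed less than POU2AF1. No biological explanation was tested. For the ARP1 value the ARP1 wildtype library stays open. A scaling factor moves all genes of a library alike, so it changes a relative median only through the added 1 and the 1 FPKM minimum. With median-ratio scaling the list stayed low, at -0.85 in ARP1 (percentile 0.19, 11 measured) and -0.66 in OCI (0.00). Fixed-total rescaling made all values smaller and left 9 measured members, with -0.39 (4.95) in ARP1 and -0.50 (0.01) in OCI. The fixed-total values therefore do not decide on scaling as a cause in either line. The OCI comparison does not use the ARP1 wildtype library.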
